A study of Homo sapiens with 24 samples.

How the data were processed

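Gene expression was measured in LNCaP cells, an established human prostate cancer line that responds to androgen, on 24 Affymetrix human expression arrays, 1 array per sample. Per the labels, cells were kept in medium with charcoal-stripped serum, which removes steroid hormones, and were treated with or without 1 nM R1881, a synthetic androgen, alone or with an inhibitor of histone deacetylases (HDACs, the enzymes that remove acetyl groups from histones and other proteins). The inhibitors were trichostatin A (TSA) at 0.1 and 1 µM, suberoylanilide hydroxamic acid (SAHA) at 0.5 and 5 µM, and LBH589 at 10 and 100 nM. All cells received cycloheximide, which blocks the synthesis of new proteins, and were harvested after 16 h. The 14 groups held 2 arrays each, except the 4 TSA groups with 1 array each. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples.

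The deposited table holds an intensity for each of 22277 probe sets on each array, on a linear scale, from 0.0282 to 17741. The values look linearly scaled per array: the mean intensity after trimming the lowest and the highest 2% of probe sets was 500.1 on every array, and no between-array quantile step or logarithm was found in the values. The software that made the intensities is not stated. The median intensity of an array lay between 116 and 138, a range of 0.22 on the log2 scale, so the values were used without further normalization. The other deposited files are experiment records of the arrays (unit: other), which hold no expression values. They were used only to find technical batches. They place the arrays on 2 scan days with 2 chip lots: 14 arrays on day 1, which are all arrays of replicate 1 and all TSA arrays, and 10 arrays on day 2, which are all arrays of replicate 2. The number of arrays limits the precision of every value below.

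Values were taken as log2(intensity + 16). The added constant damps noise near the floor and understates the fold change of dim genes. A probe set was kept when it lay above its array's median on at least 2 of the 24 arrays, which left 12833, and the 62 control probe sets were left out of the tests. Probe sets were named from the annotation supplied with the table, and 19052 symbols were matched to the reference gene table, used for names only. Of all probe sets, 19064 were assigned to 1 gene, 1043 to several genes and 2108 to none. The brightest kept probe set with a single gene name was used for each gene, which gave 7715 genes. A further 1415 kept probe sets without a single gene name were tested apart from them.

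Differences were tested with limma 3.58.1 in R 4.3.3 (tables were read with the package data.table, version 1.17.8). A mean was fitted for each of the 14 groups over all 24 arrays, so that all groups shared 1 estimate of the spread per gene with 10 residual degrees of freedom. Contrasts were tested two-sided with eBayes(trend=TRUE), which added 3.09 prior degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method within each contrast. A gene was called at an adjusted p below 0.05, and the count with at least a 2-fold change was recorded beside it. Errors of log2 differences are the standard errors (SE) of this fit. The comparisons were R1881 against no R1881 without inhibitor and at each dose of SAHA and LBH589, each dose against no inhibitor, the interaction (the R1881 effect at a dose minus that without inhibitor), and SAHA 5 µM against LBH589 100 nM. A second fit, named the replicate-blocked fit below, added the replicate number as a term and left out the TSA arrays, which carry no number (9 residual and 8.56 prior degrees of freedom). For the lower doses without R1881, no count of calls had been planned and only values of genes and lists are given. The TSA groups had 1 array each and were given as log2 differences against the mean of the arrays without inhibitor, and where stated against the array without inhibitor of day 1, on which all TSA arrays were scanned, with no test.

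A set of 25 gene lists (486 distinct genes, of which 415 were named on the array and 330 were tested) was fixed from general knowledge: androgen-induced, androgen-repressed, HDAC inhibitor-induced, HDAC inhibitor-repressed, proliferation, neuronal and neuroendocrine, HDAC enzymes, nuclear receptor cofactors, heat shock and chaperones, variant and polyadenylated histones, metallothioneins, immediate early, amino acid and ER stress, apoptosis, p53 targets, cholesterol and fatty acid synthesis, polyamine metabolism, glycolysis, antigen presentation, cancer-testis antigens, luminal epithelial keratins and adhesion, ribosomal proteins, and markers of basal epithelial cells, of fibroblasts and muscle, and of leukocytes. The 23 lists with at least 5 tested genes were tested with limma's camera at a preset correlation between genes of 0.01, again with the correlation estimated from the data, and with fry, each adjusted over the lists within a contrast. The median of a list was also set beside 10000 random lists of the same size, matched on expression in 20 bins.

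The rule for naming genes took, per comparison, up to 10 called genes with the largest rise and up to 10 with the largest fall. Only genes whose arrays did not overlap between the groups were taken for this. It also took up to 4 called members of each list with the largest change. In every comparison it took KLK3, KLK2, TMPRSS2, FKBP5, CDKN1A and HDAC1 whatever their result. The text prints part of these genes, and those taken whatever their result are not printed for every comparison. Other genes of this rule are not reported here. For interactions the genes were taken among those also called for R1881 without inhibitor. The same rule was applied to the replicate-blocked fit. The rule, the lists, the tests of genes and lists and the alternatives were fixed before the data were examined, except 3 alternatives that the closing section names. The tests of explanations were written once the patterns were seen, and the closing section names those chosen after their own result.

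The share of the androgen response kept at each dose was measured as the median log2 R1881 effect over the 57 tested genes of the androgen-induced list, and over the 21 genes called higher at least 2-fold with R1881 without inhibitor. Because genes picked and measured on the same arrays overstate their effect, genes were also chosen on 1 scan day and measured on the other. SAHA and LBH589 were each compared with the same control arrays, so the correlation of their effects was set beside 100 simulations of unchanged groups that share those controls.

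The method was tested on simulated data: in 10 simulated data sets of 7715 genes, 200 genes were changed by a known amount. For R1881 without inhibitor the fit recovered 2.84% of genes changed by 0.5, 37.6% of those changed by 1 and 83.6% of those changed by 2 on the log2 scale, with 0.121% of calls false. The replicate-blocked fit recovered 38.7%, 90.0% and 99.4% of them, with 5.18% of calls false. The data sets were drawn with a day difference per gene that was the same in all groups. The noise was normal, independent between genes, and had the spread of a fit with the day as a block. That is what the replicate-blocked fit assumes, so its share of false calls here does not show that its calls on the real arrays are true. For the interaction with SAHA 5 µM, the recovery was 0, 8.81% and 56.8%, and in the replicate-blocked fit 12.7%, 65.7% and 97.7%. Of 10 lists of 20 genes shifted by 0.5, the set test at the preset correlation found 10 for R1881, while it called 2 of 10 random lists.

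The alternatives were the replicate number as a block, the scan day as a block, quantile normalization, centring each array on its median, log2(intensity + 1) and log2(intensity + 64), no filter, a filter on probe sets whose mean lay above the median probe set, the mean over all probe sets of a gene, eBayes(trend=FALSE), leaving out each replicated array in turn, and for the kept response other choices of genes. The closing section gives their effect. Arrays were left out in the fit without a block, so the group concerned then held 1 scan day against groups of both. Raw probe-level data were not analysed here.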

Results

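Expression was measured in androgen-starved LNCaP cells given R1881, an HDAC inhibitor, both or neither for 16 h under cycloheximide. Of the 24 arrays, 20 formed 10 groups of 2 (no inhibitor, SAHA 0.5 and 5 µM, and LBH589 10 and 100 nM, each with and without R1881) and 4 were single TSA arrays. The series asks how HDAC inhibitors affect androgen-induced gene expression, and cycloheximide, which blocks protein synthesis, was present in every group. Arrays of a replicate pair correlated at 0.942 to 0.969 across genes, which are not independent replicates. The 2 arrays of each pair were scanned on 2 days with 2 chip lots, and the difference between replicates was shared between groups: it correlated across genes at 0.627 to 0.811 in all 45 pairs of groups. Within-day values and the fit with the replicate as a block are therefore printed beside the results. The control probe sets for GAPDH, a sign of RNA integrity and labelling, differed between their 3' and 5' ends by 0.60 ± 0.13 on the log2 scale (SD, n = 14) on day 1 and by -0.13 ± 0.02 (SD, n = 10) on day 2, and those for ACTB by 0.88 ± 0.18 and 0.02 ± 0.06. On day 1 the mean GAPDH difference was 0.60 on the 6 arrays at the higher doses and 0.60 on the 8 others, and on day 2 it was -0.14 and -0.12. The ACTB difference was 0.96 at the higher doses against 0.81 on the others on day 1, and 0.05 against 0.01 on day 2.

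R1881 without inhibitor raised a small set of genes, among them known androgen targets. FKBP5, a co-chaperone of steroid receptors, rose by 3.79 ± 0.41 on the log2 scale (SE, n = 2 per group), 13.8-fold, from a mean intensity of 3.82 to 271, with an adjusted p of 0.000752 from limma. GREB1, a cofactor of steroid hormone receptors, rose by 2.57 ± 0.22, the insulin signalling adaptor IRS2 by 2.49 ± 0.26, the clotting factor F5 by 2.47 ± 0.33 and the zinc finger repressor SNAI2 by 2.10 ± 0.19. SGK1, a kinase induced by steroid hormones, rose by 2.06 ± 0.23, the transcription factor MAF by 2.04 ± 0.35 and the exporter ABCC4 by 1.38 ± 0.20. The pro-apoptotic gene PMAIP1 rose by 0.94 ± 0.18. The 3 genes that fell were FOS, an immediate early transcription factor, at -1.47 ± 0.25, the mannosidase MAN1A1 at -1.16 ± 0.20 and the microtubule-binding gene MAPRE2 at -0.88 ± 0.14. FKBP5 lay near the floor of the arrays without R1881, so its fold depends on the constant added before the logarithm. The calls of FKBP5, GREB1, IRS2, SNAI2 and SGK1 were kept under every alternative. Leaving out 1 array ended the others: without replicate 1 of the untreated cells the adjusted p was 0.0748 for F5, 0.114 for ABCC4, 0.228 for MAN1A1 and 0.176 for MAPRE2. Without replicate 1 of the cells with R1881 alone it was 0.261 for MAF, 0.299 for FOS and 0.454 for PMAIP1.

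In all, 28 genes rose and 3 fell among 7715, and 21 and 2 of them changed at least 2-fold. The replicate-blocked fit called 154 higher and 72 lower, 57 and 10 of them at least 2-fold, and kept all 31. KLK3, which encodes prostate-specific antigen, had a difference of 1.46 ± 0.48 (adjusted p = 0.531), which passed in the replicate-blocked fit (adjusted p = 3.5e-05). The related kallikrein KLK2 had 2.66 ± 0.62 (adjusted p = 0.127; 0.00209 in the replicate-blocked fit), and the androgen-regulated protease TMPRSS2 had 2.18 ± 0.99 (adjusted p = 7.12e-07 in the replicate-blocked fit). CDKN1A and HDAC1 did not pass in either fit (-0.22 ± 0.19 and -0.03 ± 0.17). Genes lower only in the replicate-blocked fit included the sialyltransferase ST6GALNAC5 at -1.30, the sterol sensor INSIG2 at -1.06 and the neurotrophin BDNF at -1.06. Leaving out 1 control array changed the count: it was 6 without replicate 1 and 13 without replicate 2 of the untreated cells, and 9 and 7 without replicate 1 or 2 of the cells with R1881 alone.

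The androgen-induced list rose as a group: its median R1881 effect over 57 genes was 0.45 (mean 0.70), with 0.43 on day 1 and 0.39 on day 2, and 49 genes were positive. Of these, 7 rose and none fell, with 24 and 0 when adjusted over the list alone and 26 and 0 in the replicate-blocked fit, and the set test gave an adjusted p of 3.14e-31, or 8.59e-07 with an estimated correlation. The fry test gave an adjusted p of 7.08e-08. The immediate early list fell (median -0.18 over 14 genes, mean -0.35, adjusted p = 0.000872), with FOS as the called member of 14, but not with an estimated correlation (adjusted p = 0.0513). None of the 16 androgen-repressed genes was called by limma (median -0.04, mean -0.09, set test adjusted p = 0.687), and adjusted over the list alone 1 rose. Over all genes 314 had an unadjusted p below 0.05.

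The R1881 effect was then measured in cells given each dose. At SAHA 0.5 µM, 6 genes rose with R1881 and none fell: FKBP5 (2.91 ± 0.41), MAF (2.28 ± 0.35), GREB1 (2.17 ± 0.22), IRS2 (2.15 ± 0.26), SGK1 (1.94 ± 0.23) and SNAI2 (1.59 ± 0.19). At LBH589 10 nM, 2 rose, GREB1 by 2.08 ± 0.22 and SGK1 by 1.64 ± 0.23. At the higher doses limma called 0 genes, with 92 at an unadjusted p below 0.05 for SAHA 5 µM and 80 for LBH589 100 nM. The replicate-blocked fit called 87 higher and 33 lower at SAHA 0.5 µM, 52 and 11 at LBH589 10 nM, 6 and 0 at SAHA 5 µM and 2 and 0 at LBH589 100 nM. The 6 were MAF (1.55), the zinc finger transcription factor ZBTB16 (1.55), SGK1 (1.26), IRS2 (1.10), PMEPA1 (0.98), a membrane regulator of TGF-beta signalling, and REV3L (0.63), a DNA polymerase subunit, and the 2 were MAF (1.28) and SGK1 (0.84). The R1881 effect on FKBP5 was 0.72 at SAHA 5 µM, 1.85 at LBH589 10 nM and 0.84 at LBH589 100 nM, and that on KLK3 was 1.13 at SAHA 0.5 µM, 0.30 at SAHA 5 µM, 0.76 at LBH589 10 nM and 0.02 at LBH589 100 nM, each with an SE of 0.41 for FKBP5 and 0.48 for KLK3.

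These calls changed when single arrays were left out, which also leaves a group with arrays of 1 scan day only. The count at SAHA 0.5 µM was 3 without replicate 2 of the dose without R1881 and 0 without replicate 2 of the dose with R1881, where the adjusted p of FKBP5 was 0.248. At LBH589 10 nM it was 0 without replicate 2 of the dose with or without R1881, and 1 without replicate 1 of the dose with R1881, without either replicate of SAHA 0.5 µM without R1881 or without either replicate of SAHA 5 µM with R1881. At LBH589 100 nM it was 1 without replicate 1 of the dose without R1881.

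Measured over the androgen-induced list, the median R1881 effect was 0.447 without inhibitor and smaller at each dose: 0.271 at SAHA 0.5 µM (60.7% of that without inhibitor), 0.104 at SAHA 5 µM (23.3%), 0.200 at LBH589 10 nM (44.7%) and 0.110 at LBH589 100 nM (24.5%). On the TSA arrays it was 0.323 at 0.1 µM and 0.0816 at 1 µM, with no replicates. Within a scan day the medians were 0.433 and 0.388 without inhibitor, 0.339 and 0.300 at SAHA 0.5 µM, and 0.0632 and 0.140 at SAHA 5 µM. They were 0.194 and 0.233 at LBH589 10 nM and 0.106 and 0.0893 at LBH589 100 nM. As shares of the same day's effect without inhibitor, these were 78.4% and 77.4% at SAHA 0.5 µM and 14.6% and 36.1% at SAHA 5 µM. For LBH589 they were 44.8% and 60.2% at 10 nM and 24.5% and 23.1% at 100 nM. At SAHA 0.5 µM both day values lay above the median over both arrays. Over the 21 called genes the medians were 1.62 without inhibitor, 1.17 and 0.567 at the doses of SAHA, 0.879 and 0.515 at those of LBH589, and 1.13 and 0.428 on the TSA arrays. The list median at SAHA 0.5 µM was 0.415 without replicate 2 of that dose without R1881. Leaving out a control array also changed which genes were called, so the called-gene medians then cover other and fewer genes. Without replicate 1 of the untreated cells they were 2.36 without inhibitor, 2.16 and 0.972 at the doses of SAHA and 1.75 and 0.837 at those of LBH589. The median without inhibitor was 2.44 without replicate 1 of the cells with R1881 alone. Without replicate 2 of the cells with R1881 alone the medians were 2.24 without inhibitor, 2.04 at SAHA 0.5 µM and 1.55 at LBH589 10 nM. With 103 genes chosen on day 1 and measured on day 2 they were 0.815, 0.588, 0.118, 0.449 and 0.195 for no inhibitor, SAHA 0.5 and 5 µM, and LBH589 10 and 100 nM, and with 83 genes chosen on day 2 and measured on day 1 they were 1.04, 0.945, 0.394, 0.568 and 0.177. The list still passed the set test at each dose, with adjusted p = 4.32e-28 at SAHA 0.5 µM, 4.99e-07 at SAHA 5 µM, 1.07e-16 at LBH589 10 nM and 5.05e-05 at LBH589 100 nM, all 4 also with an estimated correlation (highest adjusted p = 0.00372). Adjusted over the list alone, 17, 2, 9 and 0 members rose, and 19, 4, 14 and 2 in the replicate-blocked fit. Immediate early genes were lower with R1881 at SAHA 0.5 µM (median -0.17, adjusted p = 0.043) and LBH589 10 nM (median -0.27, adjusted p = 0.00455), proliferation at SAHA 5 µM (median -0.17, 0.05 on day 1 and -0.39 on day 2, adjusted p = 0.00165) and ribosomal proteins at LBH589 100 nM (median -0.15, adjusted p = 5.05e-05). With an estimated correlation these had adjusted p = 0.269, 0.0973, 0.447 and 0.762.

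**Figure D1:**
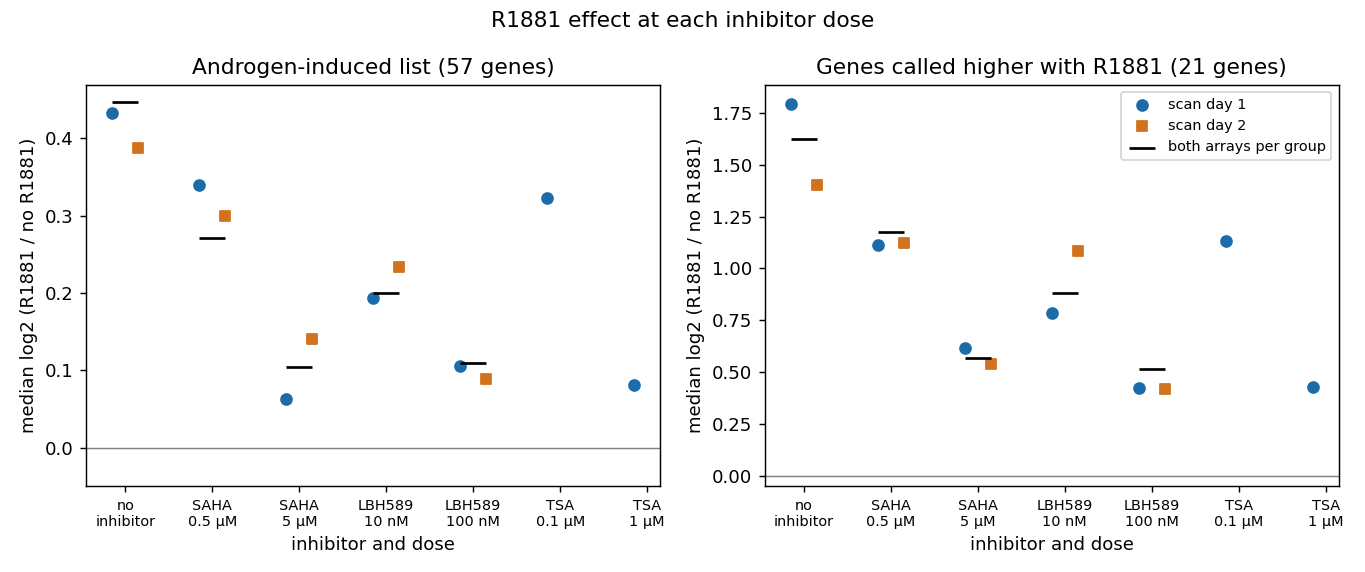
The median log2 R1881 effect of the 57 androgen-induced genes and of the 21 called genes by inhibitor and dose, over both scan days and within each. The medians of the list fall from 0.447 without inhibitor to 0.104 at SAHA 5 µM and 0.110 at LBH589 100 nM.

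The interaction tested this difference itself. Over the androgen-induced list the R1881 effect was smaller by a mean of -0.49 at SAHA 5 µM (median -0.33, adjusted p = 2.56e-16), -0.32 at LBH589 10 nM (median -0.24, adjusted p = 2.97e-09) and -0.52 at LBH589 100 nM (median -0.32, adjusted p = 5.41e-18). With an estimated correlation the adjusted p was 1.95e-05, 0.000262 and 1.23e-05. At SAHA 0.5 µM the mean was -0.15 (adjusted p = 0.0313, and adjusted p = 0.0583 with an estimated correlation). No single gene was called by limma at any dose (unadjusted counts of 33, 103, 54 and 140 for SAHA 0.5 and 5 µM and LBH589 10 and 100 nM), while 4 list members at SAHA 5 µM and 3 at LBH589 100 nM passed adjusted over the list alone. Leaving out either replicate of LBH589 10 nM without R1881 gave 1 call at SAHA 5 µM and 1 at LBH589 100 nM. The replicate-blocked fit called 3 genes higher and 18 lower at SAHA 5 µM, 3 and 30 at LBH589 100 nM, and none at the lower doses. The difference for FKBP5 was -3.07 ± 0.58 at SAHA 5 µM (adjusted p = 0.347; 0.00325 in the replicate-blocked fit) and -2.95 ± 0.58 at LBH589 100 nM. Other genes with a smaller effect in that fit at both doses were F5 (-1.78 and -2.18), TNFAIP8, a regulator of cell death (-1.84 and -1.61), GREB1 (-1.72 and -1.66), SNAI2 (-1.53 and -1.52), IRS2 (-1.40 and -1.94), TMPRSS2 (-1.80 and -1.43) and KLK3 (-1.16 and -1.45). Neuronal genes also had a smaller R1881 effect at SAHA 5 µM (median -0.30, adjusted p = 0.046) and LBH589 10 nM (median -0.37, adjusted p = 0.011), though not with an estimated correlation (adjusted p = 0.703 and 0.873). KLK2 had -2.87 ± 0.88 and -2.24 ± 0.88 and did not pass in either fit.

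**Figure D2:**
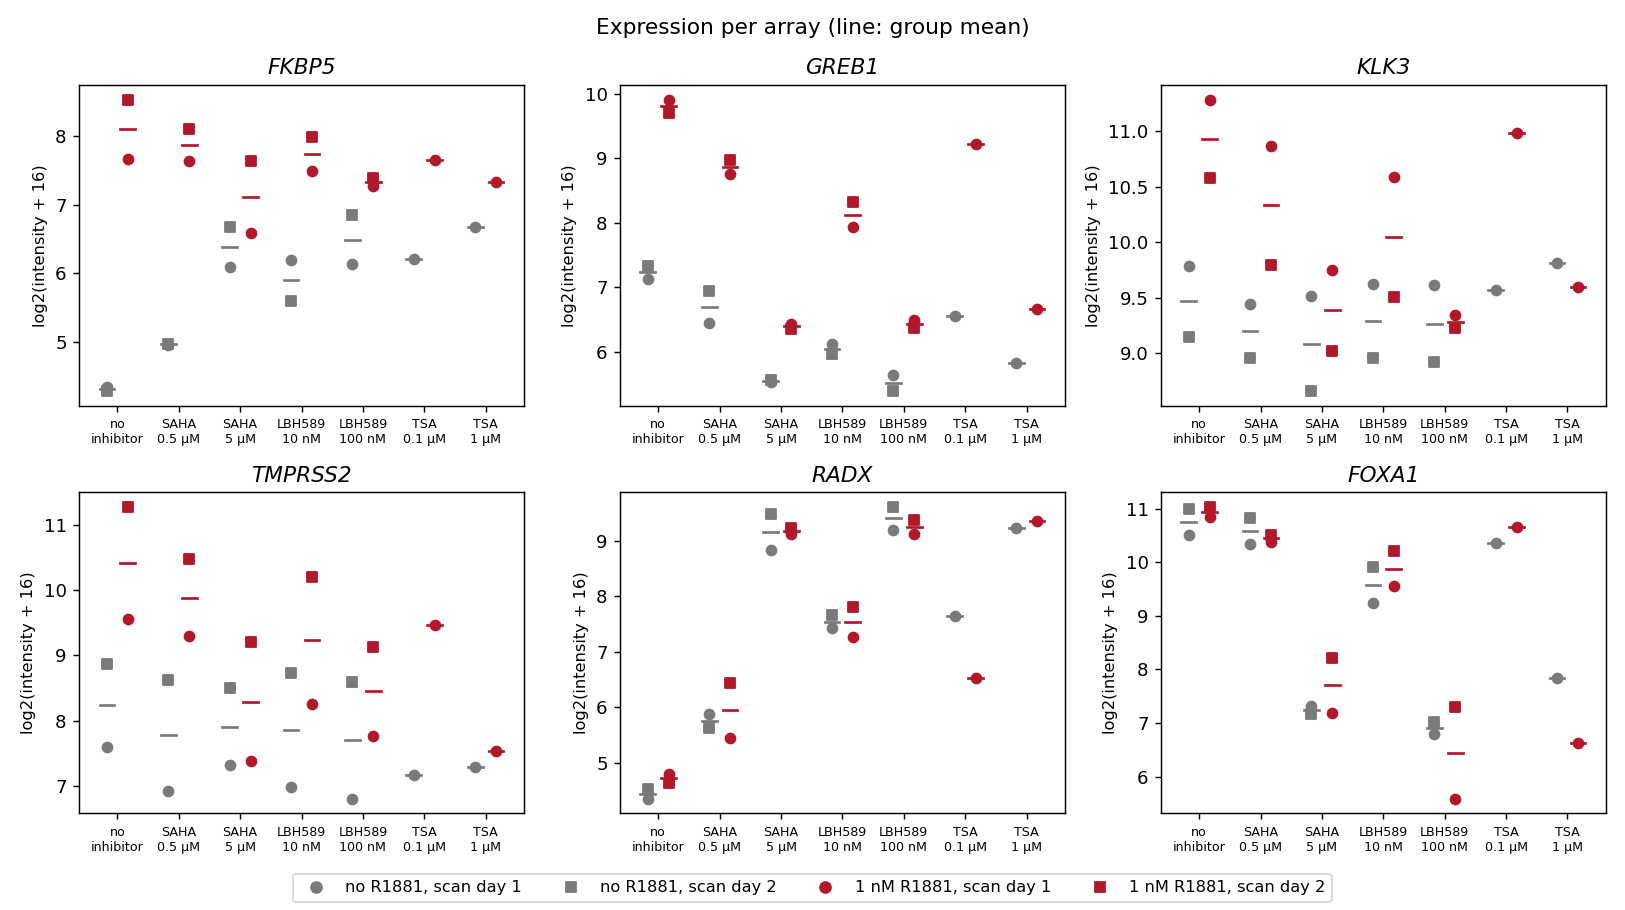
Expression of FKBP5, GREB1, KLK3, TMPRSS2, RADX and FOXA1 on each of the 24 arrays, as log2(intensity + 16), by inhibitor and dose, with and without R1881. GREB1 differed by 2.57 between the arrays with and without R1881 when no inhibitor was given, and RADX was 4.73 higher at SAHA 5 µM than without inhibitor in cells without R1881.

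SAHA at 5 µM without R1881 changed a large part of the measured genes in both directions. RADX, a regulator of DNA replication forks, rose by 4.73 ± 0.32 (SE, n = 2 per group), the fatty acid elongase ELOVL4 by 4.70 ± 0.32, the metalloproteinase inhibitor TIMP3 by 4.31 ± 0.37 and the mitochondrial aminotransferase OAT by 4.03 ± 0.18. The semaphorin and VEGF receptor NRP1 fell (-4.48 ± 0.18), as did the vasoconstrictor EDN1 (-3.77 ± 0.59), KEAP1, the sensor that targets NRF2 for degradation (-3.59 ± 0.55), and FOXA1, a pioneer transcription factor (-3.51 ± 0.47). Other kept probe sets changed less in the same direction: the 3 of TIMP3 had 1.78 to 3.68 and the 1 of NRP1 had -2.86. In all 1356 genes rose and 1187 fell, 682 and 611 of them at least 2-fold, and 2333 rose and 2173 fell in the replicate-blocked fit. Day 1 and day 2 differences correlated at 0.911 across genes. The count was 1621 without replicate 1 of the untreated cells.

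Of the 13 neuronal and neuroendocrine genes kept by the filter, 7 rose and none fell (median 0.76, with 1.05 on day 1 and 0.74 on day 2), among them the adhesion molecules NCAM1 (3.90 ± 0.42) and L1CAM (2.01 ± 0.32) and BEX1 (3.60 ± 0.38). The set test over the 13 gave an adjusted p of 0.00733 and of 0.195 with an estimated correlation. The filter keeps a dim probe set once it rises, and with no filter the 31 measured members had a median of 0.44. The 20 nuclear receptor cofactors included 7 that fell and none that rose (median -0.72, adjusted p = 0.00733; adjusted p = 0.135 with an estimated correlation): FOXA1, the acetyltransferases CREBBP (-1.94) and KAT5 (-1.79) and the coactivator NCOA2 (-1.48) were the largest. Among 12 p53 targets 7 fell (median -0.71, adjusted p = 0.0109; adjusted p = 0.135 with an estimated correlation), including the DNA damage sensor DDB2 (-1.55), the cytokine GDF15 (-1.55) and TP53I3 (-1.41). CDKN1A, the cell cycle inhibitor on this list and on the HDAC inhibitor-induced list, fell by 0.67 (adjusted p = 0.0143), and its adjusted p was 0.140 without replicate 1 of the untreated cells and 0.155 without replicate 2 of SAHA 5 µM.

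Cholesterol and fatty acid synthesis rose (7 of 18 up, none down, median 0.42, adjusted p = 0.013; adjusted p = 0.195 with an estimated correlation), with INSIG1 (2.02), which restrains sterol synthesis, the isomerase IDI1 (1.70) and the epoxidase SQLE (1.55). Of 15 chaperones 7 rose and 1 fell (median 0.33, adjusted p = 0.0302; adjusted p = 0.135 with an estimated correlation), with HSPH1 at 1.12 and BAG3 at 1.11. Luminal keratins and adhesion genes fell (4 of 9 down, none up, median -0.55, adjusted p = 0.0206; adjusted p = 0.195 with an estimated correlation), led by the claudin CLDN4 at -1.22. The HDAC inhibitor-induced list went both ways, with 6 of 22 up and 4 down (median -0.09, mean 0.20, adjusted p = 0.758): the glutaredoxin GLRX rose by 2.52, the reductase DHRS2 by 2.29 and the cell cycle inhibitor CDKN1C by 1.96, and the transcription factor KLF6 fell by 1.49. The HDAC inhibitor-repressed list had 1 up and 5 down of 13 (median -0.71, adjusted p = 0.0826), with the receptor ERBB2 at -2.45, the cyclin CCND1 at -1.57 and the methyltransferase EZH2 higher by 1.47. The androgen-induced list had 12 up and 13 down (median -0.04, mean 0.06, adjusted p = 0.849): FKBP5 rose by 2.07 ± 0.41 and EAF2, an elongation factor partner, by 2.42, and the metalloprotease ADAMTS1 fell by 2.87. KLK3, KLK2 and TMPRSS2 were not called (-0.38 ± 0.48, -0.50 ± 0.62 and -0.32 ± 0.99). The sign of the list's median changed with no filter and with the mean over probe sets.

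The other lists did not pass. Called members were 1 up and 5 down of 16 androgen-repressed genes, 6 and 5 of 32 proliferation genes (the replication helicase subunit MCM3 up by 1.87, the checkpoint kinase BUB1B at -1.41), 3 and 0 of 8 HDAC enzymes (HDAC2 up by 0.67, and HDAC1 at 0.39 ± 0.17 called only in the replicate-blocked fit, adjusted p = 0.000783), 3 and 1 of 9 histones, 1 and 2 of 14 immediate early genes, 2 and 3 of 15 amino acid and ER stress genes, 3 and 4 of 14 apoptosis genes (the apoptosome scaffold APAF1 up by 1.89, BCL2L1, a survival gene, at -2.24), 1 and 0 of 9 polyamine genes, 4 and 0 of 14 glycolysis genes (the hexokinase HK2 up by 2.71) and 2 and 0 of 12 antigen presentation genes. No metallothionein (of 7) or ribosomal protein (of 16) was called by limma, with 4 and 3 higher in the replicate-blocked fit, and the ribosomal median changed sign with quantile normalization and with median centring. Of the cancer-testis antigens 2 of 5 fell. Among markers of other cell types 1 of 7 fibroblast and muscle genes fell, ACTA2 at -2.44 (adjusted p = 0.102 without replicate 2 of the untreated cells), and of the 3 measured leukocyte genes LYZ rose by 3.22 while CD53 and LCP1 were not called. ITGA6, the 1 measured basal marker, had 0.58 ± 0.22 and was called only in the replicate-blocked fit (adjusted p = 0.0186).

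LBH589 at 100 nM without R1881 changed many of the same genes by similar amounts. RADX rose by 4.97 ± 0.32, TIMP3 by 4.70 ± 0.37, NCAM1 by 4.29 ± 0.42 and OAT by 4.15 ± 0.18, and NRP1 fell by 4.65, KEAP1 by 4.15 and FOXA1 by 3.84 (SE 0.18 to 0.55, n = 2 per group). FKBP5 rose by 2.18, DHRS2 by 2.82 and HK2 by 2.80, and CDKN1A fell by 0.87. KLK3 (-0.20 ± 0.48) and KLK2 (-0.76 ± 0.62) were not called in either fit, and TMPRSS2 (-0.54 ± 0.99) only in the replicate-blocked fit (adjusted p = 0.0186). In all 1451 genes rose and 1241 fell, 785 and 635 of them at least 2-fold, and 2473 and 2179 in the replicate-blocked fit. The lists that passed were neuronal (7 of 13 up, median 0.97, adjusted p = 0.00181), nuclear receptor cofactors (10 of 20 down, median -0.79, adjusted p = 0.00181), p53 targets (8 of 12 down, median -0.95, adjusted p = 0.00181), cholesterol and fatty acid synthesis (8 of 18 up, median 0.48, adjusted p = 0.0115), luminal genes (5 of 9 down, median -0.51, adjusted p = 0.0154) and glycolysis (5 of 14 up, median 0.36, adjusted p = 0.047). None passed with an estimated correlation: in that order, adjusted p = 0.164, 0.116, 0.0709, 0.175, 0.175 and 0.143. The 15 chaperones had 7 up and 1 down and a set test adjusted p of 0.0551. With no filter the 31 measured neuronal genes had a median of 0.74, against 0.97 for the 13 kept.

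The overlap of SAHA 5 µM and LBH589 100 nM was large. Of the genes without R1881, 1243 rose with both compounds, where 255 would be shared if the calls were independent, and 1069 fell with both, where 191 would be; RADX, NCAM1 and OAT were among the first and NRP1, KEAP1 and FOXA1 among the second. No gene was called in opposite directions. With R1881, 1127 rose with both (215 if independent) and 1001 fell with both (180). Because both compounds were compared with the same control arrays, chance alone gives a correlation: 100 simulations of unchanged groups gave a mean correlation across genes of 0.503 without R1881, against a measured correlation of 0.973. How far the shared controls raised the number of shared calls was not measured. Across arrays that shared no control, with SAHA from 1 day and LBH589 from the other, the correlation across genes was 0.911 and 0.899 without R1881 and 0.888 and 0.875 with it.

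**Figure D3:**
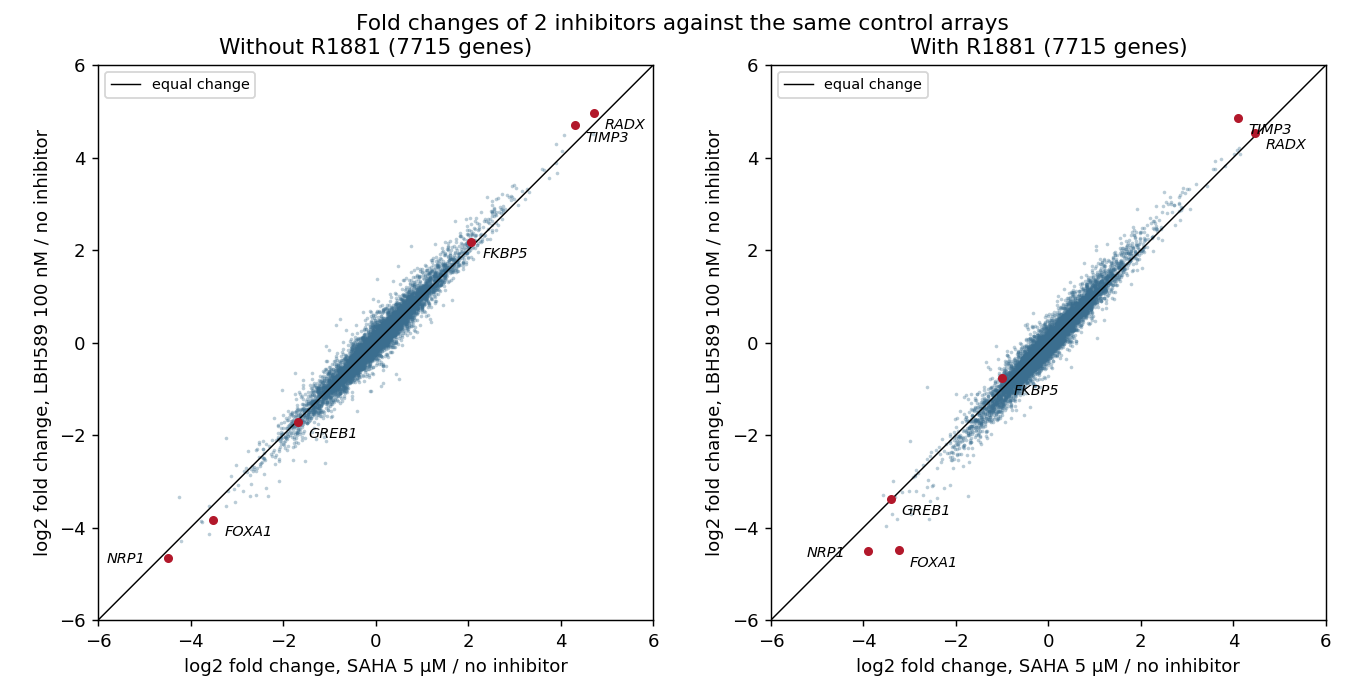
Log2 difference from no inhibitor at LBH589 100 nM against that at SAHA 5 µM for 7715 genes, without R1881 and with R1881. The correlation across genes is 0.973 without and 0.971 with R1881, where simulated unchanged groups sharing the controls give 0.503 and 0.501.

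With R1881 present, SAHA at 5 µM lowered androgen targets along with the genes above. GREB1 fell by 3.41, KLK2 by 3.36, ZBTB16 by 2.41, SPDEF, an epithelial transcription factor, by 2.13 and KLK3 by 1.55 (adjusted p = 0.0265, with 0.179 without replicate 1 of the cells with R1881 alone and 0.164 without replicate 2 of this dose), with SEs between 0.18 and 0.62 (n = 2 per group). TMPRSS2 had -2.12 ± 0.99 (adjusted p = 0.129; 5.95e-08 in the replicate-blocked fit) and FKBP5 -0.99 ± 0.41 (adjusted p = 0.0845; 0.0139 in the replicate-blocked fit). RADX rose by 4.47, NCAM1 by 4.01 and the synaptic adhesion gene NRXN3 by 3.60, while NRP1 fell by 3.91, the desmosomal cadherin DSC2 by 3.57 and FOXA1 by 3.23. CDKN1A fell by 0.62 and HDAC1 rose by 0.52 (adjusted p = 0.0224 and 0.0367), and both calls ended without replicate 1 of this dose (adjusted p = 0.141 and 0.249). In all 1200 genes rose and 1099 fell, 563 and 546 at least 2-fold, and 2249 and 2129 in the replicate-blocked fit. The androgen-induced list fell (5 up and 19 down of 57, 12 and 27 in the replicate-blocked fit, median -0.33, adjusted p = 0.0287). The androgen-repressed list fell too (1 up and 6 down of 16, median -0.39, adjusted p = 0.0339), with the CaM kinase inhibitor CAMK2N1 at -2.07 and the chemokine receptor ACKR3 at -1.97. HDAC inhibitor-repressed genes (1 up and 5 down of 13, adjusted p = 0.0359), nuclear receptor cofactors (6 of 20 down, adjusted p = 0.0235), p53 targets (4 of 12 down, adjusted p = 0.0272) and luminal genes (4 of 9 down, adjusted p = 0.0272) also fell. Neuronal genes (5 of 13 up, adjusted p = 0.0272), chaperones (7 of 15 up, adjusted p = 0.0272), cholesterol genes (7 of 18 up, adjusted p = 0.0272) and glycolysis genes (5 of 14 up, adjusted p = 0.0339) rose. None of these 10 lists passed with an estimated correlation (adjusted p = 0.104 for the lowest and 0.324 for the highest). The 13 neuronal genes kept by the filter had a median of 0.52. Over the 31 measured with no filter it was 0.22, with 0.54 on day 1 and -0.0157 on day 2. The count was 1532 without replicate 1 of the cells with R1881 alone and 1512 without replicate 1 of this dose.

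LBH589 at 100 nM with R1881 gave 1385 genes up and 1262 down, 707 and 679 at least 2-fold, and 2407 and 2275 in the replicate-blocked fit. TIMP3 rose by 4.85 ± 0.37 and RADX by 4.54 ± 0.32, and NRP1 fell by 4.51, FOXA1 by 4.49, GREB1 by 3.38, MAF by 2.43 and KLK3 by 1.65 (adjusted p = 0.0168, with 0.133 without replicate 1 of the cells with R1881 alone, and 0.0638 and 0.0797 without replicate 1 or 2 of this dose). FOS rose by 0.98 (adjusted p = 0.00935, with 0.0946 without replicate 1 of the cells with R1881 alone and 0.0845 without replicate 1 of this dose). KLK2 also fell (adjusted p = 0.00241), as did CDKN1A at -0.83 ± 0.19. TMPRSS2 had -1.97 ± 0.99 (adjusted p = 0.148; 9.34e-08 in the replicate-blocked fit). FKBP5 had -0.77 ± 0.41 and did not pass (adjusted p = 0.166; 0.0463 in the replicate-blocked fit). Androgen-induced genes fell (5 up and 21 down of 57, 12 and 28 in the replicate-blocked fit, median -0.40, adjusted p = 0.0238), as did nuclear receptor cofactors (8 of 20, adjusted p = 0.00757), p53 targets (7 of 12, adjusted p = 0.00757) and luminal genes (4 of 9, adjusted p = 0.0371). Neuronal genes (6 of 13, adjusted p = 0.00757), chaperones (8 of 15 up and 1 down, adjusted p = 0.0238) and cholesterol genes (9 of 18 up and 1 down, adjusted p = 0.0271) rose. With an estimated correlation the 7 lists had adjusted p = 0.069, 0.0787, 0.069, 0.249, 0.228, 0.0787 and 0.249 in the order given. The 13 neuronal genes kept by the filter had a median of 0.91, and the 31 measured with no filter had 0.57. The count was 1730 without replicate 1 of this dose.

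The lower doses with R1881 changed fewer genes. At LBH589 10 nM 151 genes rose and 87 fell, 61 and 39 at least 2-fold (1017 and 698 in the replicate-blocked fit). ELOVL4 rose by 3.07 ± 0.32, RADX by 2.82 ± 0.32 and NRXN3 by 2.73 ± 0.59, and the angiopoietin ANGPT2 fell by 2.62, the mitotic gene CDCA8 by 1.92, GREB1 by 1.68, SPDEF by 1.09 and ABCC4 by 0.88. KLK3 (-0.88 ± 0.48), KLK2 (-1.74 ± 0.62) and TMPRSS2 (-1.19 ± 0.99) passed only in the replicate-blocked fit (adjusted p = 0.00133, 0.0129 and 0.000268). For NRXN3, CDCA8, SPDEF and ABCC4 leaving out 1 array of the compared groups ended the call in at least 1 case (highest adjusted p 0.169 for NRXN3 without replicate 1 of this dose, 0.0928 for CDCA8 without replicate 1 of this dose, 0.0813 for SPDEF without replicate 1 of the cells with R1881 alone, and 0.221 for ABCC4 without replicate 1 of this dose). The androgen-induced list fell (1 up and 2 down of 57, 1 and 16 in the replicate-blocked fit, median -0.14, adjusted p = 0.0166; adjusted p = 0.0602 with an estimated correlation), as did androgen-repressed genes (2 of 16 down, adjusted p = 0.0406), HDAC inhibitor-repressed genes (1 of 13 down, adjusted p = 0.0246), proliferation genes (median -0.28, none of 32 called by limma, adjusted p = 0.0153) and nuclear receptor cofactors (2 of 20 down, adjusted p = 0.0246), and glycolysis genes rose (median 0.24, none of 14 called, adjusted p = 0.0246). With an estimated correlation these 5 had adjusted p = 0.128, 0.128, 0.479, 0.154 and 0.128. The count fell to 47 and 64 without replicate 1 or 2 of the cells with R1881 alone, and to 63 and 32 without replicate 1 or 2 of this dose.

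At SAHA 0.5 µM with R1881, SRPX rose by 1.21 ± 0.17 and GLRX by 1.14 ± 0.12, and the mitochondrial ribosome factor GTPBP8 fell by 1.14 (SE 0.15). These 3 calls compare with 469 genes at an unadjusted p below 0.05, and with 161 up and 108 down in the replicate-blocked fit, which included ELOVL4 (1.84), PEG10 (1.80), a retrotransposon-derived gene, SPDEF (-0.63) and CCND1 (-0.64). Both calls upward ended with another setting: SRPX had an adjusted p of 0.0916 with no filter and did not pass with log2(intensity + 64), and GLRX 0.307 with the mean over probe sets. Calls numbered 5 without either replicate of LBH589 10 nM without R1881, 0 without replicate 1 of the cells with R1881 alone or either replicate of this dose, and 1 without replicate 2 of the cells with R1881 alone. The androgen-induced list fell (median -0.14, 0 of 57 called, adjusted p = 0.0116; 0.0338 with an estimated correlation, and in the replicate-blocked fit 0.00143, but 0.122 with an estimated correlation), as did the HDAC inhibitor-repressed list (median -0.21, adjusted p = 0.04; adjusted p = 0.165 with an estimated correlation) and proliferation (median -0.17, adjusted p = 0.0283; adjusted p = 0.546 with an estimated correlation).

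The lower doses without R1881 were measured for single genes and lists. At LBH589 10 nM RADX was 3.11 ± 0.32 above the untreated cells, ELOVL4 3.27 ± 0.32 and FKBP5 1.58 ± 0.41, while GREB1 differed by -1.18 ± 0.22. Neuronal genes were higher (median 0.53, adjusted p = 0.00373), as were cholesterol genes (median 0.23, adjusted p = 0.0381). HDAC inhibitor-repressed genes (median -0.37, adjusted p = 0.0459), proliferation (median -0.23, adjusted p = 0.00373), nuclear receptor cofactors (median -0.15, adjusted p = 0.0125) and luminal genes (median -0.25, adjusted p = 0.0125) were lower. At SAHA 0.5 µM RADX differed by 1.31 ± 0.32 and ELOVL4 by 2.13 ± 0.32. Androgen-repressed genes (median -0.25, adjusted p = 0.00812), proliferation (median -0.20, adjusted p = 0.00567), amino acid and ER stress genes (median -0.15, adjusted p = 0.0441) and luminal genes (median -0.21, adjusted p = 0.00418) were lower. No list passed with an estimated correlation at either dose: the lowest adjusted p was 0.234 at LBH589 10 nM and 0.129 at SAHA 0.5 µM.

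**Figure D4:**
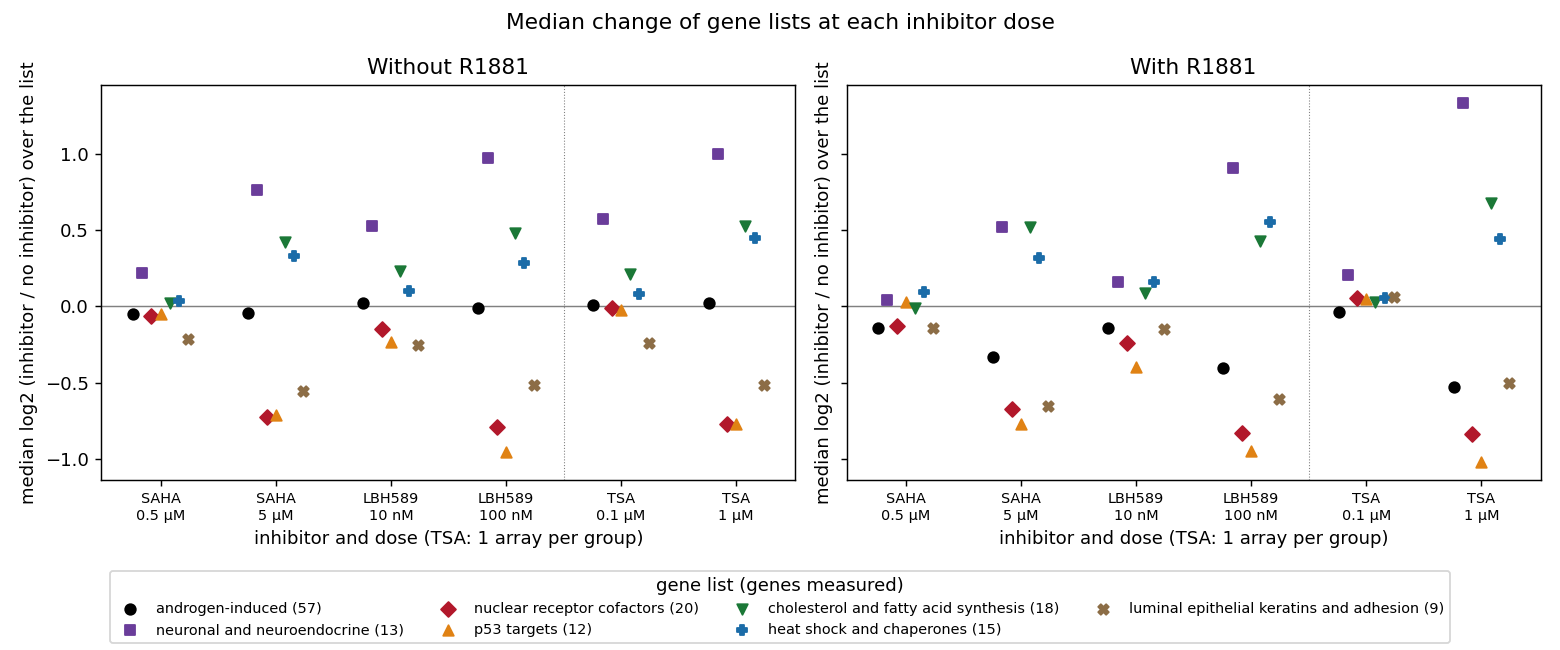
Median log2 difference from no inhibitor of 7 gene lists by inhibitor and dose, without and with R1881, where TSA points rest on 1 array per group. Without R1881 the median of the nuclear receptor cofactors is -0.72 at SAHA 5 µM and -0.79 at LBH589 100 nM, and that of cholesterol and fatty acid synthesis is 0.42 and 0.48.

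SAHA and LBH589 are both hydroxamic acids, as is TSA. Their doses were not matched, so differences between them mix compound and dose. SAHA at 5 µM and LBH589 at 100 nM gave FOXA1 differences of -3.23 and -4.49 with R1881, 1.27 apart with a 95% interval of 0.25 to 2.28 that is not adjusted over genes, and TIMP3 differences of 4.09 and 4.85, -0.76 apart (-1.56 to 0.04). The 3 other kept probe sets of TIMP3 had 0.93 to 2.97 at SAHA 5 µM and 1.41 to 3.56 at LBH589 100 nM. For GREB1 the compounds differed by -0.03 (-0.51 to 0.45) and for KLK3 by 0.10 (-0.93 to 1.13). No gene was called by limma between the compounds with or without R1881 (unadjusted counts of 115 and 84, and 641 and 458 in the replicate-blocked fit, whose smallest adjusted p was 0.136 and 0.0745). Leaving out replicate 1 of LBH589 100 nM without R1881 gave 1 call without R1881. The 95% interval of the difference lay within 2-fold either way for 75.0% of genes with R1881 and 76.0% without, and for 95.7% and 95.5% in the replicate-blocked fit. Among lists with R1881, SAHA was lower for proliferation (median -0.26, adjusted p = 8.51e-07) and neuronal genes (median -0.23, adjusted p = 0.00501) and higher for nuclear receptor cofactors (median 0.17, adjusted p = 0.0114), p53 targets (median 0.18, adjusted p = 0.0152) and ribosomal proteins (median 0.11, adjusted p = 0.0155). With an estimated correlation the adjusted p was 0.307, 0.307, 0.163, 0.163 and 0.727. Without R1881 no list passed.

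TSA at 1 µM, on 1 array per group and without a test, was set beside the other compounds at their higher doses. RADX was 4.80 higher without R1881 and 4.64 with it, TIMP3 4.86 and 5.08, and OAT 4.20 and 4.22, while NRP1 differed by -2.88 and -5.19 and FOXA1 by -2.92 and -4.31. FKBP5 differed by 2.37 without R1881 and by -0.77 with it, GREB1 by -1.40 and -3.14, and KLK3 by 0.35 and -1.33. All TSA arrays were scanned on day 1, and against the day 1 control alone RADX had 4.89 and 4.56, TIMP3 4.87 and 5.37, OAT 4.18 and 4.19, NRP1 -2.83 and -5.12, FOXA1 -2.67 and -4.22, FKBP5 2.33 and -0.34, GREB1 -1.30 and -3.25, and KLK3 0.03 and -1.69. Across genes and arrays with no shared control, TSA 1 µM correlated with SAHA 5 µM at 0.888 without R1881 and 0.842 with it, and with LBH589 100 nM at 0.906 and 0.895.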

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

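Of the tests below, all neuronal tests with no filter, the TSA tests with no shared array, the matching of levels across scan days and the Wilcoxon test and interval of a median were chosen after the result was seen. The R1881 effect on the androgen-induced list differed between cells with and without inhibitor in a direct test of the difference, while no dose was tested against another. The difference in the mean from no inhibitor was -0.49 at SAHA 5 µM, -0.32 at LBH589 10 nM and -0.52 at LBH589 100 nM. In the main fit no single gene was called over all genes, and the replicate-blocked fit called 21 genes at SAHA 5 µM and 33 at LBH589 100 nM, among them FKBP5, GREB1 and KLK3. Signals also lay in probe sets outside the gene tests, those with several gene names or none. Of these 1415, R1881 alone changed 5, all upward, SAHA 5 µM changed 306 without R1881 and 273 with it, and LBH589 100 nM changed 323 and 326.

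The first pattern weighed was the smaller R1881 effect at the higher doses. Picking genes on the arrays that measure them would shrink any later value, but genes chosen on 1 scan day and measured on the other kept at most 37.8% of the effect without inhibitor, where 80% was the limit set. A uniform shift of the arrays was small: the median interaction over all genes was 0.003 at SAHA 5 µM and -0.02 at LBH589 100 nM. The list means were -0.49 and -0.52. The highest adjusted p of the set test under quantile normalization and median centring was 1.03e-15. That test compares the list with all other genes, so median centring could hardly change it. Quantile normalization could, and the list kept its call with it. The values argued against a rise caused by the inhibitor alone only as the whole cause, and only in the androgen-induced list. Its members at least 2-fold higher with R1881 on 1 day, 17 for day 1 and 16 for day 2, had on the other day a median inhibitor effect with R1881 of at most -1.07. The highest Wilcoxon p over these genes was 0.00919, although the 95% interval of the median over resampled genes reached 0.0154 for the 16 genes, of which 11 were lower. The genes are not independent replicates, and on a day each effect rests on 1 array per group. The p and the interval therefore do not measure the spread between samples. Without R1881, 7 to 9 of these members were higher. For single genes outside the list the rise is not excluded: at SAHA 5 µM IRS2, TNFAIP8 and SNAI2 were higher by 1.73, 1.96 and 1.83 without R1881 and differed by 0.33, 0.12 and 0.30 with it. Both parts were seen for FKBP5, with 2.07 without R1881 and -0.99 with it, for F5 with 0.98 and -0.81, and for FRK with 0.90 and -0.73. The fall of these 3 with R1881 at that dose was called only in the replicate-blocked fit. As a hypothesis, these inhibitors could lower the androgen response itself, which the 3 tests above leave open. No array measured it without cycloheximide.

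The second pattern was the rise of neuronal and neuroendocrine genes. A rise of dim genes as a whole was weighed first. Among kept genes the median of the 13 members stood at the 49.7th percentile or above of random lists matched on level, and with level and effect from different days at 74.5 to 99.4. The match on level gave the outcome that the explanation had predicted. Random lists of kept genes rose too, with medians of 0.61 and 0.74 at SAHA 5 µM and LBH589 100 nM without R1881 and 0.52 and 0.64 with it. In that match the 13 members were not set apart from other kept genes of their level. This does not settle the question for all members, because the filter keeps a dim probe set once it rises. With no filter random lists had medians of 0.02, 0.16, -0.09 and -0.06, and the 31 measured members stood at the 99.5th percentile or above. There the level came from the same control arrays as the effect. With level and effect from different days they stood at the 99.74th percentile or above in 3 of the 4 comparisons, which argues against the explanation there. At SAHA 5 µM with R1881 it stays open, because on day 2 the members stood at the 91.2nd percentile. Because of the filter, the lowest median of any scan day among kept members, 0.63, and the lower percentile on the TSA 1 µM arrays, 73.3, decide nothing. With no filter scan day was excluded for 3 of the 4 comparisons, with a lowest median of 0.32. It stays open at SAHA 5 µM with R1881, where the median was 0.54 on day 1 and -0.0157 on day 2, at the 91.2nd percentile. With no filter and no array shared with day 2, both TSA 1 µM arrays stood at the 100th percentile. As that comparison did not hold on day 2, the dose as a biological explanation stays undecided for the whole pattern.

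The third pattern was the fall of p53 targets. Bright genes falling as a whole was excluded, because the list stood at the 0.36th percentile of matched random lists or below. The choice of probe set was excluded, with 0.0331 as the highest adjusted p under the mean over probe sets. The TSA 1 µM arrays placed the list at the 0.19th percentile or below, but against controls shared with the other compounds. With TSA and its control from day 1 only it stood at the 0.07th percentile or below, and on day 2 the other compounds at the 0.33rd or below, with 1 array per group. The set test did not pass with an estimated correlation. What in the treatment lowered these genes was not tested.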

How the results depend on the processing

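The alternatives chosen after seeing the data were the replicate block with quantile normalization, the replicate block with at least a 2-fold change and the replicate block with an estimated correlation. All others were planned, and all planned ones were run. Over the 47 main counts and values, 851 of 1095 alternatives left the result unchanged by the following rules, and 244 did not. A count was unchanged when it stayed within 1.5-fold of the main count. A median was unchanged when it moved by less than the SD between the 2 scan days, for TSA that of the values without inhibitor. A set test was unchanged when it kept its direction and its side of 0.05. Over the 640 results of named genes, 18677 of 19737 alternatives left the call unchanged, 606 ended it, 454 added it and none turned it to the other direction. In both totals most alternatives left out 1 array. Where that array lay outside the groups compared, the difference between them could not move and only the shared spread could. Neither total therefore measures how well a result holds. The androgen-induced list kept its smaller R1881 effect at SAHA 5 µM, LBH589 10 nM and LBH589 100 nM, and its R1881 effect at every dose, under each of the 10 alternatives run for the set tests, which were not repeated with an array left out. Except where a sentence says so, the cause of a change was not tested.

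Counts of called genes rose most with a block. Under the replicate block they were 226 for R1881, 4506 and 4652 for SAHA 5 µM and LBH589 100 nM without R1881, and 269, 4378, 1715 and 4682 for SAHA 0.5 µM, SAHA 5 µM, LBH589 10 nM and LBH589 100 nM with R1881. The R1881 effect within those 4 doses gave 120, 6, 63 and 2, the interactions with SAHA 5 µM and LBH589 100 nM 21 and 33, and the genes shared by the 2 compounds numbered 4088 without and 4011 with R1881. The median effect of the called genes was 1.02, 0.383 and 0.309 at SAHA 0.5 µM, SAHA 5 µM and LBH589 100 nM, and 6 lists passed for SAHA 0.5 µM with R1881. With the scan day as the block the counts, in the same order, were 227, 4506, 4655, 271, 4381, 1714 and 4676, then 120, 6, 61 and 2, then 21 and 30, and 4093 and 4013 shared. With the replicate block and quantile normalization they were 229, 4551, 4711, 324, 4428, 1806 and 4757, then 124, 6 and 69 for R1881 at SAHA 0.5 µM, SAHA 5 µM and LBH589 10 nM, then 19 and 34, and 4167 and 4064 shared. The replicate block with at least a 2-fold change gave 67, 1505, 1629, 35, 1305 and 1597 (without LBH589 10 nM), then 40, 4, 19 and 1, then 16 and 24, which is lower than the block alone because a threshold was added.

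The strict filter tests fewer genes. It left 1 call for R1881 at LBH589 10 nM and 6 lists for SAHA 0.5 µM with R1881, and the median of the androgen-induced list was 0.313 without inhibitor and 0.0781 at LBH589 100 nM. The called genes had 1.07 at SAHA 0.5 µM and 0.329 at SAHA 5 µM, and the list's interaction with SAHA 0.5 µM no longer passed (adjusted p = 0.125). With no filter that p was 0.161, the list medians were 0.302, 0.159 and 0.0809 at SAHA 0.5 µM, SAHA 5 µM and LBH589 100 nM and 0.380 and 0.1197 on the TSA arrays, and the called genes had 1.20 and 0.552 at SAHA 0.5 µM and LBH589 100 nM. The mean over probe sets gave 4 calls for R1881 at LBH589 10 nM, 1 for the interaction with LBH589 100 nM, and 6 and 3 lists for SAHA 5 µM and LBH589 10 nM with R1881. The called genes then had 1.16, 0.413 and 0.475 at SAHA 0.5 µM, SAHA 5 µM and LBH589 100 nM, and the list 0.141 at LBH589 100 nM and 0.278 at TSA 0.1 µM.

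With log2(intensity + 64) each of those 2 interactions had 1 call, the list median was 0.402 without inhibitor, and the called genes had 1.10, 0.478 and 0.466. With log2(intensity + 1) the called genes had 1.24 at SAHA 0.5 µM and 0.522 at LBH589 100 nM. Median centring gave list medians of 0.395, 0.242, 0.255 and 0.141 for no inhibitor, SAHA 0.5 µM, LBH589 10 nM and LBH589 100 nM and 0.0347 at TSA 1 µM, called-gene medians of 1.21 and 0.590 at SAHA 0.5 µM and LBH589 100 nM, and an adjusted p of 0.0516 for the interaction with SAHA 0.5 µM. Quantile normalization gave called-gene medians of 1.14, 0.426 and 0.435, list medians of 0.134 at LBH589 100 nM and 0.265 at TSA 0.1 µM, and 6 lists for SAHA 0.5 µM with R1881. With an estimated correlation, which widens the spread the set test assumes, 1 list passed for R1881, 1 for SAHA 0.5 µM with R1881, and 0 for SAHA 5 µM and LBH589 100 nM without R1881 and for SAHA 5 µM, LBH589 10 nM and LBH589 100 nM with it. The interaction with SAHA 0.5 µM then had 0.0583, and with the replicate block added 0.294 with 0 lists passing in each of the 6 inhibitor comparisons.

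On day 1 alone the list median was 0.339 at SAHA 0.5 µM, and the called genes had 1.11 there and 0.424 at LBH589 100 nM. On day 2 alone the list had 0.388, 0.300, 0.233 and 0.0893 for no inhibitor, SAHA 0.5 µM, LBH589 10 nM and LBH589 100 nM, and the called genes 1.12 and 0.421. A day holds no residual degrees of freedom, so its values carry no test. Keeping only called members of the list gave 1.38, 1.07, 0.278, 0.829 and 0.392 for no inhibitor, SAHA 0.5 and 5 µM and LBH589 10 and 100 nM. Genes chosen on replicate 1 gave 0.815, 0.588, 0.118, 0.449 and 0.195, and those chosen on replicate 2 gave 1.04, 0.945, 0.394, 0.568 and 0.177, where 103 and 83 genes took the place of the 21. With no fold threshold for the called genes they had 0.940, 0.316 and 0.288 at SAHA 0.5 µM, SAHA 5 µM and LBH589 100 nM.

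Leaving out 1 array leaves its group with 1, which is assumed to vary like the others. These fits had no block, and the remaining array comes from 1 scan day while the other replicated groups cover both. Part of the difference between days then enters the comparison. A changed count or median therefore mixes the scan day with the array left out. The R1881 count was 6 to 32: 6 and 13 without replicate 1 or 2 of the untreated cells, and 9 and 7 without replicate 1 or 2 of the cells with R1881 alone. SAHA 5 µM without R1881 had 1621 (without untreated replicate 1) to 2552, and with R1881 1512 to 2272 (1512 without its own replicate 1, 1532 without replicate 1 of R1881 alone). LBH589 100 nM without R1881 had 1855 to 2700, and with R1881 1730 (without its own replicate 1) to 2682. SAHA 0.5 µM with R1881 had 0 to 5: 5 without either replicate of LBH589 10 nM without R1881, 0 without replicate 1 of R1881 alone or either replicate of its own, and 1 without replicate 2 of R1881 alone. LBH589 10 nM with R1881 had 32 to 239: 47 and 64 without replicate 1 or 2 of R1881 alone, and 63 and 32 without its own replicate 1 or 2. R1881 at SAHA 0.5 µM had 0 to 9 (3 and 0 without replicate 2 of that dose without or with R1881), at LBH589 10 nM 0 to 3 and at LBH589 100 nM 0 to 1 (1 without replicate 1 of that dose without R1881). At LBH589 10 nM the 0 came without replicate 2 of that dose with or without R1881, and 1 came without replicate 1 with R1881, either SAHA 0.5 µM array without R1881 or either SAHA 5 µM array with it. The interactions with SAHA 5 µM and LBH589 100 nM had 0 to 1 (1 without either replicate of LBH589 10 nM without R1881), and SAHA 5 µM against LBH589 100 nM without R1881 had 0 to 1 (1 without replicate 1 of LBH589 100 nM). The shared genes numbered 1506 (without untreated replicate 1) to 2322 without R1881 and 1404 (without replicate 1 of R1881 alone) to 2108 with it.

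The list medians, leaving out 1 array, were 0.392 to 0.530 without inhibitor, 0.271 to 0.415 at SAHA 0.5 µM, 0.154 to 0.279 at LBH589 10 nM and 0.0972 to 0.147 at LBH589 100 nM. The highest at SAHA 0.5 µM, more than 1.5 times the reported median, came without replicate 2 of that dose without R1881. The called-gene medians were 1.62 to 2.44 without inhibitor, 1.01 to 2.16, 0.448 to 0.972, 0.833 to 1.75 and 0.429 to 0.837 at SAHA 0.5 and 5 µM and LBH589 10 and 100 nM, with the highest without replicate 1 of R1881 alone for no inhibitor and without replicate 1 of the untreated cells at every dose, where fewer genes were called. Without replicate 1 of the untreated cells the median without inhibitor was 2.36. Without replicate 2 of R1881 alone the medians were 2.24 without inhibitor, 2.04 at SAHA 0.5 µM and 1.55 at LBH589 10 nM. Signal over background limits dim genes such as FKBP5 without androgen, and the arrays cannot resolve folds that start at the floor.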

Other observations

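TSA at 0.1 µM, on 1 array per group and untested, gave other values with R1881 than without it. Against the control of the same scan day its array without R1881 gave RADX 3.30, OAT 2.43 and FKBP5 1.87 above the untreated cells. With R1881 the values were 1.73, 1.27 and -0.02. The array with R1881 also had the highest GAPDH difference between 3' and 5' ends of all arrays, 0.819 against 0.476 without R1881. Its ACTB difference was not the highest: it was 0.946 against 0.714 without R1881, where day 1 arrays had a mean of 0.876 and a maximum of 1.20. RNA quality and R1881 are not separated here. Across genes the correlation of TSA 0.1 µM with SAHA 5 µM was 0.681 without R1881 and 0.282 with it, on arrays with no shared control, and with LBH589 100 nM it was 0.666 and 0.249. Genes are not independent replicates.

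Metallothioneins, small metal-binding proteins, did not pass the camera test in the main or the replicate-blocked fit. No member was called in the main fit, and the replicate-blocked fit called 4 at SAHA 5 µM and 6 at LBH589 100 nM without R1881 and 4 at each with it. In that fit the fry test passed in all 4 comparisons (highest adjusted p = 0.0329). Fry does not compare a list with other genes, and in that fit 56.7% to 60.7% of all 7715 genes were called in these comparisons. Its pass therefore does not set this list apart. Their median was 0.50 at SAHA 5 µM and 0.63 at LBH589 100 nM without R1881, and 0.58 and 0.64 with it, at percentiles of 96.8, 98.9, 98.9 and 99.1 of random lists matched on level. On the TSA 1 µM arrays it was 0.67 and 0.79, and 1.03 and 1.19 against the control of the same scan day. Nuclear receptor cofactors stood at the 0.04th percentile or below and cholesterol and fatty acid synthesis at the 99.8th or above in the same comparisons. The HDAC inhibitor-induced list lay between the 30.6th and the 61.6th. The metallothionein median at LBH589 100 nM with R1881 was the value of MT1F, whose other kept probe set had -0.28. At SAHA 5 µM with R1881 MT1F had 0.50 and its other probe set -0.17, and without R1881 they had 0.46 and 0.13. The other probe set of MT1X had 0.68 to 0.84 in the 4 comparisons.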
